A study of Mus musculus with 6 samples.

How the data were processed

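Olfactory epithelium RNA of 3 homozygous and 3 heterozygous OMP-GFP samples was hybridised to Affymetrix mouse 430 2.0 arrays after 1-cycle biotin labelling, per the labels. The deposited intensity values are MAS5 signals per probe set on a linear scale, per the submitters' processing notes, whose version and settings are not given in the sources used here. The 2% trimmed mean of the deposited values was 500 on every array, so the arrays were taken as already scaled and were not scaled further. Detection calls were not used here, so no probe set was called absent.

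The table holds 45101 probe sets on 6 arrays, of which 64 are controls. The platform annotation names 1 gene for 34958 probe sets, several for 932 and none for 9211, and covers 18194 genes. Probe sets with several genes were not named. Gene neighbours of Omp were taken from a RefSeq table of assembly GRCm38.p6, used only for names and for which genes neighbour each other, since no genome build is given for the values.

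Values were analysed as log2(value + 38.8), the offset being the 25th percentile of all values pooled, so fold changes of dim probe sets are understated. Probe sets whose mean log2 value was at or above the median over all probe sets were tested, leaving 22514 after the controls were set aside. The groups were compared with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes with an intensity trend and Benjamini-Hochberg adjustment at 0.05. The test had 4 residual degrees of freedom and a prior of 6.68, and the median SE of a difference was 0.11 on the log2 scale. For genes, the probe set of highest mean among those that name 1 gene was used, giving 11426 genes. No 2 arrays held identical values beyond 101 of the 45101 probe sets.

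There were 38 gene lists: 33 had at least 5 measured members and were tested with camera (preset correlation 0.01, two-sided), 4 had fewer, and the sex-linked genes were given per array only. The 4 not tested were lymphocyte markers with 4 measured members, skeletal muscle markers with 3, and vomeronasal and trace amine-associated receptors with 0 each. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives.

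The genes named were fixed by a rule before the data were examined: Omp at every probe set, then the 10 genes of largest change in each direction past adjustment. Places left open were filled with genes at unadjusted p under 0.05 whose groups did not overlap. From each list described, up to 4 members were named, the 2 of lowest p and the 2 of highest mean signal. For lists given only as a mean, no member was named. Ratios of 3-prime to 5-prime control probe sets were compared with an exact permutation test.

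The alternatives were other offsets, quantile or median scaling, no filter or a stricter one at the 75th percentile, other variance models, a replicate block, each array left out in turn, a plain pooled-variance test, a threshold of 0.1, the mean of all probe sets per gene and other list tests. Chosen after seeing the data were leaving out the libraries labelled heterozygous 1 and 3 together and the Eif2s3y signal as a covariate.

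The probe set test was tested on simulated data, 5 runs of 22514 probe sets with 200 changed in each and independent noise. For homozygous against heterozygous with 3 and 3 arrays it recovered 55.1% of changes of 1.41-fold, 96.8% of 2-fold and 100% of 4-fold changes, with 62 false calls over all runs beside 177, 334 and 328 changes recovered at these sizes. The list test, on 11426 genes, found 1 list shifted by log2 0.3 in 20 of 20 runs, with 0 other lists called. Simulated noise was independent between genes, unlike that of real arrays. Changes were added alike to all arrays of a group, so these recoveries do not hold where 1 array departs from its group. At Omp probe set 1422199_at, where that was so, a log2 difference of -4.74 had a limma adjusted p of 0.859.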

Results

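Gene expression was measured in the olfactory epithelium, the nasal sheet that holds the odour-sensing neurons, of mice carrying the OMP-GFP allele. Olfactory marker protein, encoded by Omp, is an abundant cytosolic protein of mature olfactory sensory neurons. In the OMP-GFP line, as background knowledge, the coding sequence of Omp is replaced by that of green fluorescent protein, so homozygous mice make no olfactory marker protein and heterozygous mice keep 1 intact allele. The comparison addressed how olfactory marker protein affects transcript levels in this tissue. The groups also differ in the number of GFP copies and there was no wild-type group. An effect of olfactory marker protein therefore cannot be told apart from one of GFP. There were 3 arrays labelled homozygous and 3 labelled heterozygous, each from 1 RNA sample hybridised to the Affymetrix mouse 430 2.0 array. The median MAS5 signal per array lay between 147.9 and 163.7, and the number of arrays limits the precision of every difference. The labels do not say whether each RNA came from 1 animal or a pool, so the tests measure the spread between these samples. Sex-linked transcripts, given below, argue against 1 animal as the source of some of these samples.

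The targeted gene was examined first, because a probe set within its replaced part would check the labels. Omp is represented by the probe sets 1422199_at and 1422200_at. The signal of 1422199_at was 5.7, 8.8 and 31.3 in homozygous 1, 2 and 3. It was 26.3 in the library labelled heterozygous 1, 4664 in heterozygous 2 and 9143 in heterozygous 3. The library labelled heterozygous 1 therefore lies with the homozygous arrays at this probe set, while its label was kept in every comparison. Whether that goes against its label depends on where the probe set lies in the gene, which is not known here. The difference for 1422199_at was -4.74 ± 1.38 on the log2 scale (homozygous minus heterozygous, SE), with an adjusted p of 0.859 in limma. Without the library labelled heterozygous 1 it was -6.96, with an adjusted p of 4.89e-06. The homozygous signals lie below the offset of 38.8 added before the log, so these sizes depend on the offset, and with the pooled-median offset the difference over all arrays was -3.56. Over all the alternatives that kept this probe set, it stayed lower in homozygous arrays.

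The other probe set of Omp, 1422200_at, has the higher mean signal. It read 8280 ± 443 in homozygous and 8332 ± 371 in heterozygous arrays (SD, n = 3 each), a difference of -0.01 ± 0.06 on the log2 scale (SE), with a limma adjusted p of 0.994. Where either probe set lies relative to the replaced part of the gene is not given in the labels. A probe outside that part checks nothing, so neither probe set is an established check of the labels, and 1422200_at was not used as one.

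**Figure D1:**
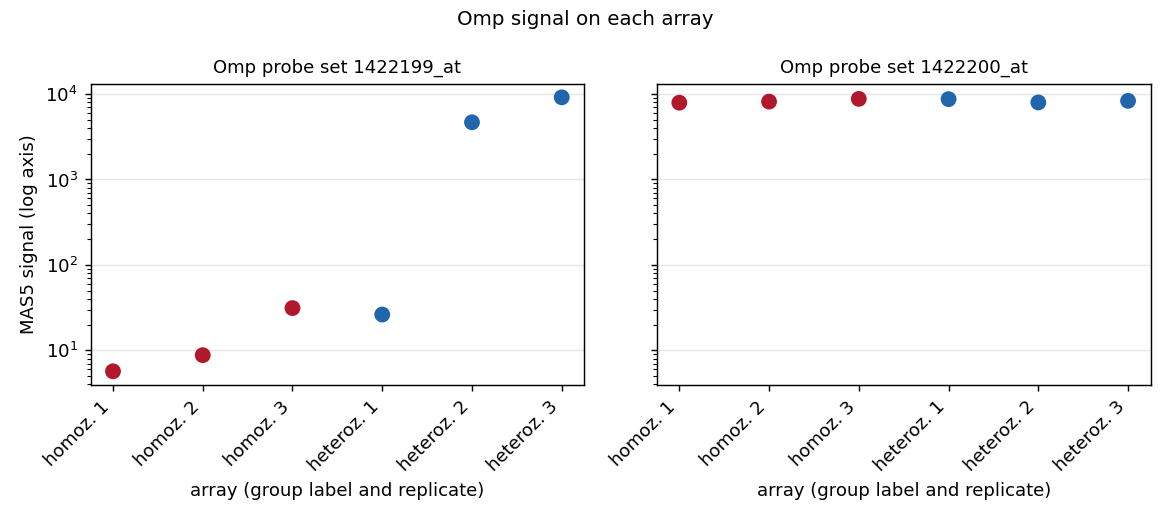
MAS5 signal (log axis) of both Omp probe sets on each of the 6 arrays, red for homozygous and blue for heterozygous labels, 1 point per array. For 1422199_at the library labelled heterozygous 1 (26.3) lies with the homozygous arrays (5.7 to 31.3), while 1422200_at lies between 7918.5 and 8774 on all arrays.

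No probe set passed adjustment between the groups. Of 22514 probe sets tested with limma, 0 passed an adjusted p of 0.05, and the lowest adjusted p was 0.474. A plain pooled-variance test called 0 as well. At an unadjusted p under 0.05 there were 1291 probe sets, beside 1126 expected by chance, and 67 of them differed by at least 1.5-fold, 23 higher and 44 lower in homozygous arrays. Of the 1291, 751 were higher and 540 lower in homozygous arrays, a share of 58.2% higher. That share was 29.1% when arrays were shifted to a common median and 50.8% after quantile normalization. Without the library labelled heterozygous 1, 25 probe sets passed, 3 higher and 22 lower in homozygous arrays. Leaving out the libraries labelled heterozygous 1 and 3 together, an alternative chosen after seeing the data, gave 30. Without homozygous 2 the unadjusted count was 744, and without heterozygous 3 it was 2101.

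The genes of largest difference are given as values, since none of them passed. They were filled in from genes with an unadjusted p under 0.05 and no overlap between groups. Groups did not overlap for 1181 of 11426 genes, or 10.3%, where chance gives 10% for 3 against 3. Adat2, a subunit of the tRNA adenosine deaminase, read 724.0 ± 19.97 in homozygous and 439 ± 155 in heterozygous arrays (SD, n = 3 each), a log2 difference of 0.73 ± 0.19 (SE). Eomes, a T-box transcription factor of projection neurons in the olfactory bulb, read 474 ± 31.3 against 299 ± 88.8, with a log2 difference of 0.64 ± 0.17, which was 0.42 without heterozygous 3 and 0.12 at its other probe set. The sialyltransferase gene St6galnac1 differed by 0.62 and Tmem87a by 0.59. Cxcl5, a neutrophil-attracting chemokine, differed by 0.57, and Tnmd, which encodes the tendon protein tenomodulin, by 0.57. Icam1, an adhesion molecule, differed by 0.55, the transcriptional repressor Zeb2 by 0.53, with 0.14 at its other probe set, the tight junction gene Cldn4 by 0.53 and Mpzl3 by 0.53. With the pooled-median offset Icam1 differed by 0.35, and without the libraries labelled heterozygous 1 and 3 Cxcl5 differed by 0.38. The limma adjusted p of these 10 genes lay between 0.689 and 0.951.

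Among the genes chosen by this rule that were lower in homozygous arrays, Efhd2, which encodes a calcium-binding protein, had the largest difference. It read 465 ± 77.1 in homozygous and 1752 ± 1208 in heterozygous arrays (SD, n = 3 each), a log2 difference of -1.58 ± 0.40 (SE). Its signal was 635 in the library labelled heterozygous 1, 1589 in heterozygous 2 and 3033 in heterozygous 3. Its other probe set kept in the test differed by -0.05, so the probe sets of this gene disagree. Tcf7l1, a transcription factor of the Wnt pathway, differed by -0.86, with -0.00 at its other probe set. It differed by -0.55 without homozygous 1, and by -0.0033 with no offset and -0.015 after quantile normalization, where the other probe set had the higher mean and stood for the gene. Klhl7 differed by -0.68, Prkar1b, a regulatory subunit of protein kinase A, by -0.67, and Ugt8a, which makes the myelin lipid galactosylceramide, by -0.67. Without heterozygous 3 the difference of Prkar1b was -0.31. Without the library labelled heterozygous 1, in which the myelin genes Mbp and Pmp22 read 7268.5 and 4899, that of Ugt8a was -0.40. At their other probe sets Klhl7 differed by -0.11, Ugt8a by -0.12, Prkar1b by -0.62 and Fgl2 by -0.41. Atpsckmt differed by -0.64, the integrin gene Itgb3 by -0.61, Cthrc1 by -0.60, Pigt by -0.59 and Fgl2 by -0.58. With the pooled-median offset Itgb3 differed by -0.38, and without the libraries labelled heterozygous 1 and 3 Prkar1b differed by -0.44. Their adjusted p in limma lay between 0.748 and 0.951. Without the library labelled heterozygous 1, Efhd2 had a gene-level adjusted p of 0.0188.

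**Figure D2:**
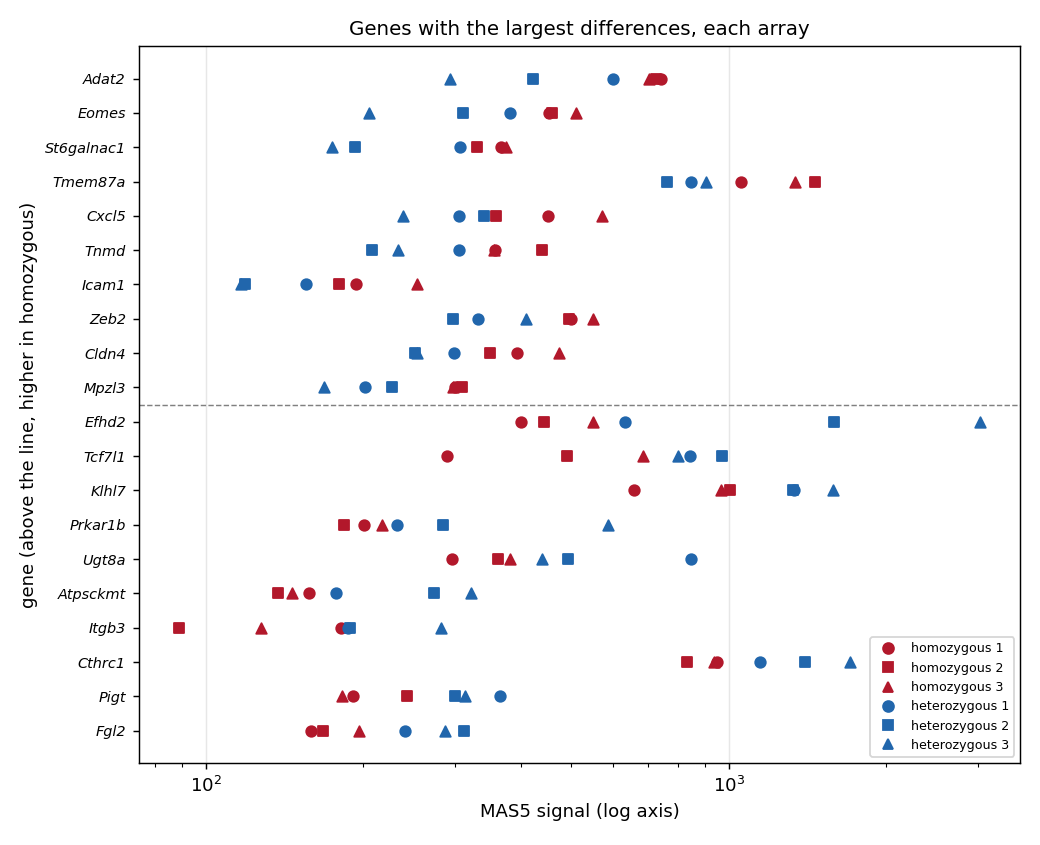
MAS5 signal (log axis) on each array of the 20 genes named for their difference, red for homozygous and blue for heterozygous labels, with a marker shape per replicate number. Genes above the dashed line were higher in homozygous arrays, and none passed adjustment; Efhd2 ranges from 635 to 3033 over the heterozygous arrays.

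Gene lists fixed before the data were examined were then compared. Of 33 lists, 13 passed an adjusted p of 0.05 in camera with a preset correlation of 0.01, 9 shifted up and 4 down in homozygous arrays. With an estimated correlation 0 passed, the lowest adjusted p being 0.341, and 0 passed with fry. No member of any list passed adjustment over all genes. Adjusted over the list alone, 1 member in all the lists passed, Eomes among the olfactory bulb and brain markers. Means per list below are log2 differences, homozygous minus heterozygous, over the measured members, with the SD over members. The arrays of the groups did not overlap for 5 of the 13 lists.

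Markers of blood and immune cells were shifted up on average, but the arrays of the groups overlapped for each of these lists. Against its mean over the arrays, the neutrophil list lay at -0.125 in homozygous 2 and 0.037 in heterozygous 2. The estimated correlations were 0.148 for the macrophage, 0.173 for the neutrophil and 0.425 for the erythroid list, above the preset 0.01 used in camera. The macrophage and dendritic cell list had a mean of 0.14 ± 0.12 with 21 of 23 members higher, at a camera adjusted p of 0.000198 and an adjusted p of 0.341 with an estimated correlation. At an unadjusted p under 0.05 5 members were higher and 0 lower. The leukocyte phosphatase gene Ptprc read 416 ± 19.6 against 329 ± 25.8 and the endotoxin co-receptor gene Cd14 read 488 ± 42.4 against 393 ± 11.04 (SD, n = 3 each). Csf1r and Lgmn, the brightest members, differed by 0.05 and 0.04. The list's mean was 0.087 without heterozygous 3, and 0.031 with a camera adjusted p of 0.525 without the libraries labelled heterozygous 1 and 3, in a range of adjusted p from 2.1e-06 to 0.525 over the alternatives. The neutrophil and marrow precursor list had a mean of 0.31 ± 0.21 with 9 of 10 members higher, at adjusted p values of 0.000821 in camera and 0.341 with an estimated correlation. In that list S100a9 differed by 0.53, S100a8 by 0.43, Anxa1 by 0.19 and Ltf by 0.03. Without the libraries labelled heterozygous 1 and 3 this list had a mean of 0.12 and a camera adjusted p of 0.191, in a range from 9.22e-08 to 0.5005 over the alternatives. The 6 measured erythroid markers had a mean of 0.35 ± 0.27 with all 6 higher, at a camera adjusted p of 0.00767 and an adjusted p of 0.378 with an estimated correlation. Among them Alas2, the first enzyme of haem synthesis in red cells, differed by 0.53, Hbb-b2 by 0.36, Car2 by 0.21 and Tfrc by 0.19. Without homozygous 1 the erythroid mean was 0.13 and its camera adjusted p 0.309, in a range from 1.38e-05 to 0.525 over the alternatives.

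Markers of vessels, skeleton and glands were also shifted up. The endothelial and stromal list had a mean of 0.13 ± 0.15 with 13 of 16 members higher, at adjusted p values of 0.000821 in camera and 0.341 with an estimated correlation. Kdr, a receptor for vascular endothelial growth factor, differed by 0.44, Vwf by 0.39, and the bright members Rgs5 and Col3a1 by 0.06 and 0.04. Without the library labelled heterozygous 1 its mean was 0.080 and its camera adjusted p 0.087, in a range from 0.000278 to 0.411 over the alternatives. Bone and cartilage markers had a mean of 0.09 ± 0.12 with 14 of 16 members higher (camera adjusted p 0.0148; adjusted p = 0.341 with an estimated correlation), and included Col10a1 at 0.38, Cnmd at 0.34, Col1a2 at 0.07 and Col1a1 at 0.04. Bowman gland and nasal gland genes had a mean of 0.17 ± 0.22 with 18 of 20 higher (camera adjusted p 0.0153; adjusted p = 0.355 with an estimated correlation). The bright secretory genes Bpifb9b and Bpifa1 differed by 0.0014 and -0.02, Bpifb3 by 0.15 and Lcn3 by 0.52. Lipocalins and urinary proteins had a mean of 0.32 ± 0.27 with 7 of 8 higher (camera adjusted p 0.0475; adjusted p = 0.341 with an estimated correlation), and Obp1a differed by 0.31 and Lcn11 by 0.13. Respiratory and motile cilia markers had a mean of 0.08 ± 0.09 with 18 of 21 higher. This list, called the cilia list below, had a camera adjusted p of 0.0148, and of 0.434 with an estimated correlation. In it Rfx3, a transcription factor of ciliated cells, differed by 0.22, Ccdc39 by 0.21, Reg3g by 0.18 and Dynlrb2 by 0.0048.

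The calls of these last lists were lost without single arrays. Bone and cartilage markers had camera adjusted p values of 0.106 without homozygous 1, 0.101 without homozygous 3 and 0.087 without the library labelled heterozygous 1, in a range from 0.00212 to 0.411 over the alternatives. The gland list had 0.411 without homozygous 3, 0.247 without the library labelled heterozygous 1 and 0.0555 without heterozygous 3, in a range from 0.000918 to 0.598. The lipocalin list had 0.363 without homozygous 3, 0.519 with a mean of 0.20 without the library labelled heterozygous 1 and 0.0516 without heterozygous 2, in a range from 0.00124 to 0.519. The cilia list had 0.0795 without homozygous 2, 0.135 without homozygous 3, 0.117 without the library labelled heterozygous 1 and 0.0872 without heterozygous 3, in a range from 0.000718 to 0.584. Single members rested on single arrays too. Lcn3 differed by 0.098 without heterozygous 2, and without the library labelled heterozygous 1 Obp1a differed by 0.099, Vwf by 0.23 and Anxa1 by 0.12 and Lcn11 reversed to -0.29. With 1 array left out Obp1a reached 0.60, Lcn11 0.34 and Tfrc 0.42. Without homozygous 3 Ltf reversed to -0.18 and Dynlrb2 to -0.0525, and Reg3g fell to 0.099. Without homozygous 1 Alas2 fell to 0.25, S100a8 to 0.26, Car2 to 0.063 and Csf1r to 0.026. Tfrc fell to 0.063 without heterozygous 2, and without heterozygous 3 Hbb-b2 fell to 0.19, Col10a1 to 0.195, Cnmd to 0.21, Bpifb3 to 0.042 and Col3a1 to 0.0016. Bpifb9b and Lgmn also changed sign in at least 1 of these settings.

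Neuronal lists moved in both directions. Olfactory transduction genes, which carry the odour response in neuronal cilia, had a mean of 0.13 ± 0.16 with 12 of 16 members higher, at adjusted p values of 0.00218 in camera and 0.397 with an estimated correlation. The G protein subunit genes Gnb1 and Gnal differed by 0.41 and 0.18, Slc12a2 by 0.18 and Gng13 by 0.05. Gnb1 read 8571 in heterozygous 3, 11990.5 in heterozygous 2 and 16894 in the library labelled heterozygous 1, and without heterozygous 3 its difference was 0.17, that of Gnal 0.11 and that of Gng13 -0.065. That of Gnb1 was 0.65 without the library labelled heterozygous 1, and that of Slc12a2 0.12 without homozygous 2. Without heterozygous 3 the list's mean was 0.04 and its camera adjusted p 0.177, in a range from 1.55e-06 to 0.525 over the alternatives. Without the library labelled heterozygous 1 its mean was 0.22. Synaptic vesicle genes had a mean of -0.12 ± 0.15 with 21 of 26 members lower (camera adjusted p 0.0012; adjusted p = 0.341 with an estimated correlation). Vamp2, a vesicle fusion protein gene, differed by -0.44, Rab3a by -0.30, Stx1a by -0.11 and Snap25 by -0.06. Stx1a differed by -0.028 without the library labelled heterozygous 1, and without heterozygous 3 Rab3a differed by -0.17, Stx1a by -0.19 and Snap25 by 0.025. Without heterozygous 3 the adjusted p of this list was 0.0776, in a range from 1.86e-05 to 0.718. In heterozygous 3 this list lay 0.13 above its mean over the arrays and the olfactory bulb and brain list 0.18 above, and the neuronal genes Rbfox3 and Cplx1 read 791 and 738 there, against 49.5 to 184 and 140.0 to 308 on the other arrays. Calcium extrusion and buffering genes had a mean of -0.07 ± 0.09 with 16 of 22 lower (camera adjusted p 0.0308; adjusted p = 0.355 with an estimated correlation), with Bex1 at -0.18, Calb2 at -0.17, S100a5 at -0.13 and Atp2a2 at 0.03. Its adjusted p was 0.215 without homozygous 1, 0.0531 without homozygous 2 and 0.3002 without heterozygous 3, in a range from 0.00454 to 0.5005. Its mean was -0.025 without heterozygous 3 and -0.10 without the library labelled heterozygous 1. Atp2a2 changed sign without heterozygous 3. Bex1 and S100a5 of this list are also among the mature neuron markers, which did not pass as a list.

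Lists of younger neurons were shifted down by small amounts. Neuronal progenitor markers had a mean of -0.06 ± 0.11 with 9 of 13 members lower (camera adjusted p 0.0361; adjusted p = 0.341 with an estimated correlation). Nhlh1 differed by -0.19, Insm1 by -0.19 and Sox11 by 0.01. Immature neuron markers had a mean of -0.05 ± 0.10 with 20 of 31 lower (camera adjusted p 0.0361; adjusted p = 0.522 with an estimated correlation), with Tubb3 and Marcksl1 both at -0.14, Atf5 at -0.05 and Stmn1 at 0.05. The progenitor list had adjusted p values of 0.0822 without homozygous 1, 0.135 without homozygous 3, 0.140 without the library labelled heterozygous 1 and 0.104 without heterozygous 3, in a range from 0.0125 to 0.440. The immature neuron list had 0.146, 0.123, 0.402 and 0.3002 without the same libraries in that order, in a range from 0.000763 to 0.525. Its mean was -0.084 without heterozygous 2 and -0.023 without heterozygous 3, and leaving out the libraries labelled heterozygous 1 and 3 together turned it to 0.03. Sox11 and Atf5 changed sign when single arrays were left out. Without the library labelled heterozygous 1, Stmn1 differed by 0.07, but by -0.50 at another probe set, 1448113_at, which passed there in limma (adjusted p 0.0475).

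The size of these list shifts also depended on scaling, filter and summary. With arrays shifted to a common median, list means were 0.035 for the cilia list, 0.049 for bone and cartilage and 0.083 for endothelial markers. They were -0.089 for immature neurons, -0.106 for progenitors and -0.107 for calcium genes, and all 6 calls were kept. After quantile normalization the calls of the immature neuron (camera adjusted p 0.277), progenitor (0.0569), calcium (0.0569) and lipocalin lists (0.0513) were lost. The pooled-median offset also ended that of the lipocalin list (0.0547). With no filter the bone list had a mean of 0.052 (0.171), the gland list 0.12 (0.106) and the calcium list -0.135 (0.00454). With the stricter filter the bone list had 0.051 (0.0588), the immature list -0.036 (0.0835) and the endothelial list 0.066 (0.0182), and the erythroid list had no value. With the mean of all probe sets per gene the immature list had -0.012 (0.245), the synaptic list -0.064 (0.0666), the cilia list 0.052 (0.163) and the lipocalin list 0.33 (0.0964). The erythroid list again had no value there. Without the libraries labelled heterozygous 1 and 3, chosen after seeing the data, the synaptic list had -0.038 (0.718), the cilia list 0.019 (0.584) and the gland list 0.082 (0.598). There the calls of the erythroid (0.121), endothelial (0.121), progenitor (0.440), calcium (0.198) and lipocalin lists (0.0828) were lost as well.

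**Figure D3:**
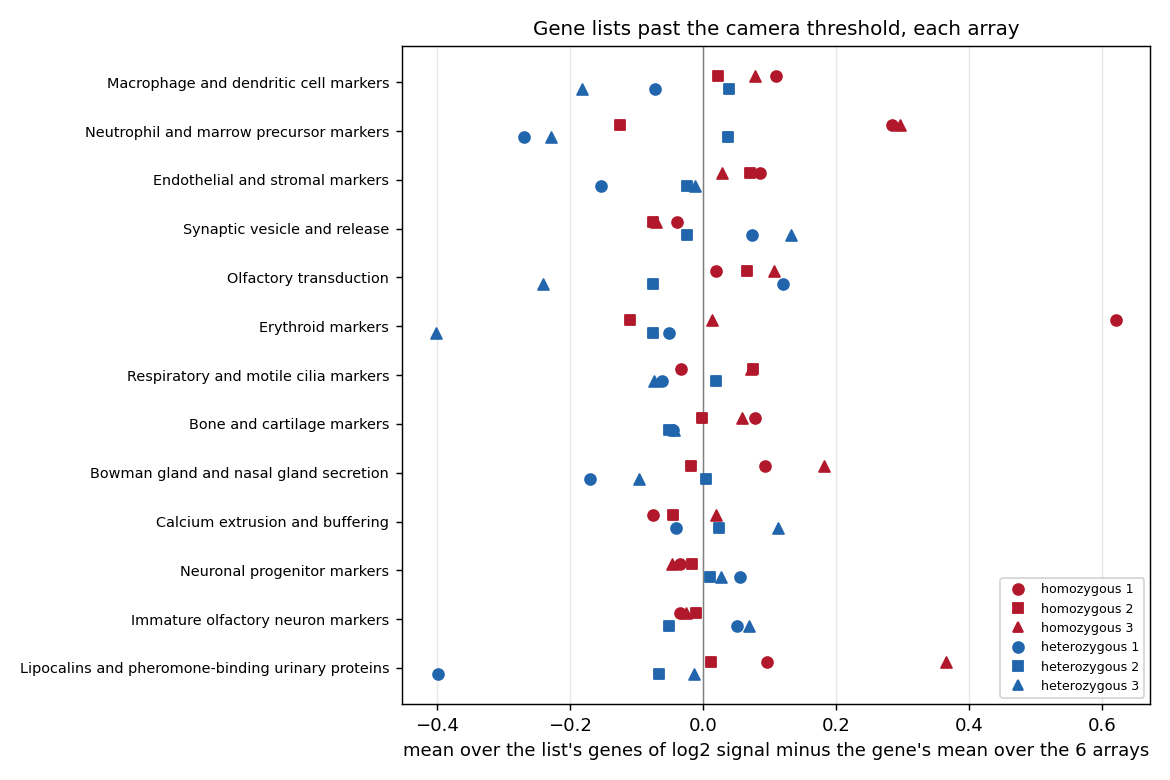
Mean over each list's genes of log2 signal minus the gene's mean over the 6 arrays, for the 13 lists past the camera threshold, red for homozygous and blue for heterozygous labels, with a marker shape per replicate number. Erythroid markers reach 0.62 in homozygous 1 and -0.40 in heterozygous 3, and transduction genes -0.24 in heterozygous 3.

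The markers of mature neurons did not pass. Their mean was 0.01 with 9 of 25 members higher, a median of -0.03 and a camera direction of down, so mean and test differ in sign (adjusted p 0.624). Uchl1 differed by -0.19, Bex1 by -0.18, S100a5 by -0.13 and Stoml3 by 0.10, which reversed to -0.012 without heterozygous 3. The 16 measured odorant receptors had a mean of 0.06 (adjusted p 0.247), with Olfr544 at 0.44, Olfr65 at 0.35, Olfr672 at 0.16, or 0.049 without heterozygous 2, and Olfr749 at 0.04, which changed sign when single arrays were left out. Sustentacular cell markers had a mean of -0.02 (camera adjusted p 0.730), with 10 members higher and 12 lower. The bright detoxification gene Cbr2 read 24125 ± 56.6 against 23701 ± 920 (SD, n = 3 each). Cyp2j6 differed by -0.18, or -0.070 without the library labelled heterozygous 1. Cyp4b1 differed by -0.16 and Gpx6 by 0.06, or -0.054 and 0.0087 without heterozygous 2. The 106 measured genes within 10 megabases of Omp on chromosome 7 had a mean of 0.01 (adjusted p 0.781), a median of -0.01 and 48 members higher and 58 lower, with Olfml1 at 0.41, Ppfibp2 at 0.34, Plekhb1 at -0.07, or -0.029 without the library labelled heterozygous 1, and Rps3 at 0.01, which changed sign there. Activity-dependent neuron genes had a mean of -0.00, axon guidance genes 0.04, and cyclic nucleotide enzymes and protein kinase A subunits 0.01.

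The other lists did not pass either. Horizontal basal cell markers had a mean of 0.10, immediate early genes 0.08, microvillar cell and ionocyte markers 0.06, interferon-stimulated genes 0.04 and cell cycle genes 0.03. Some of these rest on single arrays. Against their means over the arrays, immediate early genes lay at 0.209 in homozygous 3 but below 0 in homozygous 1 and 2. Cell cycle genes lay at 0.122 in homozygous 1 and -0.083 in homozygous 3, and interferon-stimulated genes at 0.215 in heterozygous 2 and -0.144 in heterozygous 3. Ensheathing glia and Schwann markers had a mean of -0.17 with an SD of 0.40 over members. This rests on the library labelled heterozygous 1, where the list lay 0.46 above its mean over the arrays, and below it on every other array. Heat shock genes had a mean of -0.05, oxidative phosphorylation genes -0.02, unfolded protein response genes 0.02, olfactory bulb and brain markers -0.01, apoptosis regulators -0.01, oxidative stress and xenobiotic response genes 0.01 and cytosolic ribosomal protein genes -0.00.

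Sex-linked genes varied between arrays, and their values overlapped between the groups. Xist, from the inactive X chromosome, read 112, 5727 and 10210.3 in homozygous 1, 2 and 3 at probe set 1436936_s_at. It read 7041 in the library labelled heterozygous 1, 9957 in heterozygous 2 and 8164 in heterozygous 3. The Y-linked gene Eif2s3y read 1485, 1060 and 8.0 in homozygous 1, 2 and 3 at 1417210_at. It read 435 in the library labelled heterozygous 1, 32.8 in heterozygous 2 and 533 in heterozygous 3. Homozygous 2, heterozygous 3 and the library labelled heterozygous 1 thus had both transcripts. A single animal would not normally carry both an inactive X and a Y chromosome. These values therefore argue against 1 animal as the source of each of these RNAs. The samples also differed in their mix of sexes, which the labels do not give. Eif2s3y averaged 851 ± 760 in homozygous and 334 ± 265 in heterozygous arrays (SD, n = 3 each). With its signal as a covariate, chosen after seeing the data, 0 probe sets passed adjustment and 14 lists passed in camera. An effect of this mix on the differences above is not excluded.

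Control probe sets for RNA integrity showed no difference beyond replicate spread. The log2 ratio of 3-prime to 5-prime signal was -0.45 ± 0.04 in homozygous and -0.49 ± 0.03 in heterozygous arrays for Gapdh (SD, n = 3 each; two-sided exact permutation p = 0.3). For Actb it was 0.38 ± 0.02 in homozygous and 0.38 ± 0.03 in heterozygous arrays (two-sided exact permutation p = 0.6). The smallest p that 3 against 3 allows is 0.1.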

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

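The libraries left out together and the Eif2s3y covariate were chosen after seeing the data. The count past adjustment stayed at 0 except for 1 with the pooled-median offset (unnamed probe set 1455869_at), 0 to 25 when 1 array was left out, and 30 without the libraries labelled heterozygous 1 and 3 together, which leaves a lone heterozygous array assumed to vary like the rest. The 25 came without the library labelled heterozygous 1, and 17 of them are among the 30. The call without homozygous 3 was Mtmr7. The count at unadjusted p of 1291 was 2456 with no filter and 585 with the stricter one, since more or fewer probe sets were tested, 744 to 2101 with 1 array left out, and 2219 without both libraries. The 1.5-fold subset of 67 was 115 with no offset, 30 with the pooled-median offset, 580 with no filter, 13 with the stricter filter, 76 to 177 with 1 array left out and 328 without both libraries. The 13 lists were 0 with an estimated correlation and 0 with fry, 9 with quantile scaling, 10 with the stricter filter, 11 with the mean of all probe sets, 12 with the pooled-median offset and with no filter, 6 to 13 with 1 array left out, 7 without both libraries and 14 with the covariate. For the remaining changes the cause was not tested.

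The difference of Omp at 1422200_at, -0.01, lay within its SE of 0 and changed sign to 0.0054 with quantile scaling, in a range from -0.052 to 0.023 with 1 array left out, and 0.054 without both libraries. At 1422199_at it ranged from -6.96 to -3.39 with 1 array left out, passing there only without the library labelled heterozygous 1, and was -6.47 without both libraries. The filters with no offset and at the 75th percentile removed this probe set. The Gapdh ratio difference kept its sign, and that of Actb, -0.01, ranged from -0.024 to 0.0023 with 1 array left out. The immature neuron list reversed to 0.028 without both libraries.

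With a replicate block the count past adjustment was 0, at unadjusted p 1106, in the 1.5-fold subset 79, and the lists 13. Same-numbered arrays had deviation correlations of 0.02, -0.12 and -0.05, and no homozygous array matched its own number best. No pairing by number was thus detected, though so few arrays cannot show that the numbers mark no shared litter or day. The 20 named genes kept their sign where they had a value, which under the stricter filter only 5 had. Tcf7l1 was -0.0033 with no offset and -0.015 with quantile scaling, where another probe set stood for the gene. Adjusted over genes, only Efhd2 passed, in 2 settings; adjusted over probe sets, those of Efhd2, Adat2 and Cthrc1 are among the 25. Low signals near background limit the dim probe sets, where the offset sets the fold.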

Other observations

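All the tests of explanations here were chosen after the results were seen. Single libraries carried transcripts of other cell types, named here after their values were seen. In the library labelled heterozygous 1, the myelin genes Mbp and Pmp22 read 7268.5 and 4899, against 655 to 1038 and 851 to 1206 on the other arrays, and the Ensheathing glia and Schwann list lay 0.46 above its mean. That library also had the lowest Mup5 signal, 518. In heterozygous 3, Meg3 read 924 at its probe set of largest gap, against 46.7 to 196 on the other arrays. Rbfox3, a neuronal splicing factor, read 791 against 49.5 to 184, and the olfactory bulb and brain list lay 0.18 above its mean. Camk2a read 458 there, but is not among the probe sets at least 2-fold apart from all other arrays. In heterozygous 2, Chil4, a chitinase-like protein gene of type 2 inflammation, read 2445 against 74.8 to 160 elsewhere. In homozygous 1, the red cell gene Slc4a1 read 945.0 at its brightest probe set. At least 2-fold apart from all other arrays were 22 probe sets in heterozygous 3, 17 in the library labelled heterozygous 1, 10 in homozygous 1, 7 in heterozygous 2, 3 in homozygous 3 and 1 in homozygous 2.

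The near-background signal of Omp at 1422199_at in the library labelled heterozygous 1 was weighed first. A swap with a homozygous library would put a high signal in that group, where the highest was 31.3. A failed array would lower 1422200_at too, which read 8708.7 in the library labelled heterozygous 1. Degraded RNA could spare 1422200_at, since where the Omp probe sets lie is not known, so this signal does not exclude it. The log2 control ratios of 3-prime to 5-prime signal had an SD of 0.03 over the heterozygous arrays for both Gapdh and Actb. No heterozygous array thus stood far apart in them. On the 24 other probe sets called without that library, its median position was 0.00668, where 0 is the homozygous mean and 1 that of heterozygous 2 and 3, and 23 of 24 lay nearer the homozygous mean. Choosing probe sets without a library itself pulls that library toward the other group: on the 24 of lowest p without heterozygous 2 or 3, none past adjustment, the medians were 0.324 and 0.224, with 13 and 16 nearer. In both of these the library labelled heterozygous 1 helped to choose the probe sets and to set position 1. They are therefore not a like reference for 0.00668. A wrong genotype label, or homozygous source animals, is a candidate explanation, and a genetic background that heterozygous 2 and 3 share but this library lacks stays open.

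The 25 probe sets called without the library labelled heterozygous 1 were weighed next. Besides Omp they include Rps9, Prune2, Psmd6, Prdx2 and Khdrbs1, on 11 chromosomes in all for the 17 named ones, with 0 of the 106 measured neighbours of Omp among them. Of 14 with other probe sets for the gene, 13 had others that moved by less than 0.5 of the called one, Miat being the exception at 0.70, but 4833420G17Rik came near it with -0.51 against -1.03. The median difference at the other probe sets was -0.00471, against -1.89 at the called ones, which argues against a change of the whole gene's expression for the 12 whose others moved by less than 0.25 of it. A sequence or transcript variant under single probe sets, such as differing strain background, may account for these 12, but the labels name no strain and probe sequences were not used here. Of the 21 lower in homozygous arrays, Omp left out, 19 read higher in heterozygous 3 than in heterozygous 2. At Omp 1422199_at the signal of heterozygous 2 above the homozygous mean was 50.9% of that of heterozygous 3. Over those 21 this share had a median of 63.4%, from 32.0% to 147%, so Omp 1422199_at lay within their range.

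The upward shift of blood and immune lists was weighed last. A lower share of olfactory neurons in the homozygous libraries would raise the markers of all other cell types alike, by at least 0.14 on the log2 scale, the smallest of these list means. The sustentacular markers had a median of -0.0127 with an SD of 0.076 over members, and a difference over arrays of -0.021 ± 0.055 (SE). These lie below 0.14, but that size was taken as fixed although it is itself uncertain. It is the mean of the macrophage and dendritic cell list, whose arrays overlapped between the groups. Its deviations were 0.110, 0.023 and 0.079 in homozygous 1, 2 and 3. They were -0.071 in the library labelled heterozygous 1, 0.040 in heterozygous 2 and -0.181 in heterozygous 3. A test run before this one set the neutrophil list against the sustentacular list by array (gap 0.33, SDs 0.24 and 0.14, two-sided exact permutation p = 0.2) and left the question open. The later test does not settle it. Neither test used the neurons' own transcripts, and these went both ways in homozygous arrays. Mature neuron markers had a mean of 0.01, transduction genes 0.13 and Omp 1422200_at a difference of -0.01. Synaptic vesicle genes had a mean of -0.12 and immature neuron markers -0.05. A lower share of neurons is therefore not excluded. Blood left in the tissue and an effect of genotype on immune cells stay open and untested.

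The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. A real count of 0 past adjustment is reached by any split, so the 10 that reach it test nothing, and the highest other was 2. At unadjusted p, 3 splits reached 1291, the highest other being 1836, and for the 1.5-fold subset 4 reached 67, the highest other being 78. For lists 1 split, the real one, reached 13, and the highest other was 11.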
